A study of Mus musculus with 9 samples.

How the data were processed

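RNA was measured in GFP+ cells of the embryonic mouse cortex (strain C57BL/6). Short hairpin RNAs (shRNAs) were brought into the cortex by in utero electroporation at embryonic day 13.5, and the tissue was collected at embryonic day 15.5, 48 hours later. Electroporated cells were isolated by FACS, RNA was extracted with Trizol, and libraries were prepared with Illumina TruSeq after polyA selection. There were 3 groups with 3 biological replicates each. The first received 3 shRNAs against circSlc45a4, a circular RNA named after the Slc45a4 gene, the second received 2 shRNAs against the linear Slc45a4 mRNA, and the third received 1 scrambled sequence (scramble). A circular RNA has no polyA tail and polyA selection does not retain it, so its level was not read, and no value is given for it.

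The deposited table holds whole read counts per gene, without normalization, for 53379 gene IDs in 9 libraries. Every column was used. The submitters' notes name bcl2fastq 2.17.1.14, STAR 2.4.2a, DESeq2 and the mouse build mm10, without the role or order of each. The annotation release, the strand setting, the counting program and any filter applied by the authors are not given in the sources used here. The versioned Ensembl IDs were joined to GENCODE release M21 (GRCm38, the same assembly as mm10) without their version suffix. A symbol was found for 53274 IDs and none for 105, and 50604 IDs matched with their version unchanged. Coordinates come from that annotation.

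Total counts ranged from 21073174 to 45469298 per library. Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10, by group), which left 17760 genes, and libraries were scaled by trimmed mean of M-values (TMM). Values are given as CPM, each count divided by its library's TMM-scaled total. A quasi-likelihood model with 1 term per group was fitted to all 9 libraries (6 residual degrees of freedom), so that the comparisons share their estimate of the spread, and each of the 3 pairs of groups was tested with the F test of edgeR. Benjamini-Hochberg adjusted p under 0.05 counts as a call. Standard errors are the log2 fold change divided by the square root of F. The common biological coefficient of variation was 13.9%. A count of 0 allows up to 3 counts, which is 0.0660 CPM in the deepest and 0.142 CPM in the shallowest library. Reads without molecular identifiers are not independent molecules, so this floor covers counting error only. The test was checked on simulated data with 200 changed genes per comparison. Changes of 1.5-fold were recovered in 50% (circSlc45a4 knockdown against scramble), 43% (Slc45a4 mRNA knockdown against scramble) and 55% (direct comparison) of 100 genes, and changes of 2-fold in 78%, 60% and 67%. Among the unchanged genes 8, 6 and 15 were called. In the direct comparison these false calls were a larger share of all calls than the nominal 0.05.

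Before the data were examined, 37 gene lists, the comparisons, the tests and the rule for naming genes were fixed. The lists cover cell types of the cortex and its surroundings (apical and basal progenitors, newborn, deep-layer, upper-layer, Cajal-Retzius, subplate and ventral inhibitory neurons, oligodendrocyte precursors, microglia, endothelial cells, pericytes, meningeal fibroblasts, erythroid cells, choroid plexus with cortical hem). They also cover neurogenic transcription factors, signalling (Notch, Wnt, Hedgehog, axon guidance), synapses, the cell cycle (S phase, G2 and M phase, exit inhibitors, p53 targets, replication-dependent histones) and stress (interferon, immediate early genes, unfolded protein response, hypoxia). The others are small RNA machinery, mitochondrially encoded genes, the respiratory chain, ribosomal proteins, glycolysis, cholesterol synthesis and the SLC45 family. Of 759 symbols in the lists, 40 stand in more than 1. Each list was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, 2-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. It was tested again with the correlation estimated from the data, and with the rotation test fry, which asks whether the genes of a list move on balance 1 way and does not compare them with other genes. Member counts are given over all genes tested and adjusted over the list alone.

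The rule names Slc45a4, and in each comparison the 12 largest rises and 12 largest falls among genes past the threshold whose 2 groups do not overlap and whose average log2 CPM is at least 1, without predicted models. It also names up to 4 members of each list with the smallest p, and 6 genes called in both knockdowns. Some genes that the rule names are not reported here. Agreement between the knockdowns was compared with 20 sets of counts simulated for unchanged groups against the same scramble libraries.

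Alternatives fixed beforehand were size factors by the DESeq2 method (RLE), upper-quartile factors, limma-voom, the Wald test of DESeq2 1.42.0, no filter, a filter on 1 CPM in 3 libraries, only the 6 libraries compared, the replicate number as a block, a minimum change of 1.2-fold (glmTreat), no mitochondrial or haemoglobin genes, and each library left out in turn. Added after seeing the data were thinning of all libraries to the smallest total, the Xist level as a covariate, removal of trends on GC content and gene length, and several of these settings for the lists. Correlations between libraries with the same replicate number, after the group means were removed, lay between -0.141 and 0.115. They were -0.141 to 0.034 where 1 of the libraries was scramble. Between the 2 knockdowns they were 0.083, 0.081 and 0.115, against -0.071 to -0.028 for unlike numbers. Unlike numbers with a scramble library ranged from -0.120 to 0.177, a spread that covers these values. A shared day or litter of the knockdown libraries was therefore neither shown nor excluded. The labels do not name one, so the main model left pairing out and the replicate block was run as an alternative.

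Short sequence words were searched in the annotated 3' UTRs of 11209 genes with at least 50 bases of 3' UTR and an average log2 CPM of at least 1. The words most tied to low expression in 1 group were chosen in a random part of the genes, compared with 100 permutations, and tested in the held-out part of equal size, with UTR length and GC content and coding length and GC content as covariates. The words chosen in this way and 6-base words chosen over all genes were also looked up in coding sequences. The shRNA sequences were not used. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.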

Results

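The study set knockdown of a circular RNA, circSlc45a4, beside knockdown of the linear mRNA of the same gene in cells of the embryonic cortex. Each of the 3 groups held 3 libraries. Total counts were 45449574, 36883510 and 45469298 in replicates 1, 2 and 3 of the circSlc45a4 knockdown, 35307378, 37051161 and 35818896 in those of the Slc45a4 mRNA knockdown, and 21073174, 30788165 and 31833779 in those of scramble. The first principal component (34.9% of the variance) set the circSlc45a4 knockdown apart from the other groups, and the second (19.7%) set the Slc45a4 mRNA knockdown apart from scramble. The sex of the pooled embryos differed between libraries. Xist, the RNA of the inactive X chromosome, stood at 635, 264 and 428 CPM in the circSlc45a4 knockdown and at 1550, 637 and 0.194 CPM in the Slc45a4 mRNA knockdown, against 0.239, 0.0648 and 0.0618 CPM in scramble. The Y-linked gene Ddx3y was read at 20.01 to 41.6 CPM in 8 libraries and at 0 counts in Slc45a4 mRNA knockdown replicate 1. Xist differed between the groups, and calls that ended with its level as a covariate are given beside their values.

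Slc45a4 (ENSMUSG00000079020.9, chromosome 15, positions 73577424 to 73645762, minus strand, GRCm38) encodes a member of the SLC45 sugar transporter family and is the targeted locus. Its linear transcript stood at 31.4, 33.6 and 33.96 CPM in scramble, at 25.4, 25.3 and 24.7 CPM in the circSlc45a4 knockdown and at 13.3, 18.5 and 17.4 CPM in the Slc45a4 mRNA knockdown. In the Slc45a4 mRNA knockdown it fell to 16.4 ± 2.77 CPM from 33.0 ± 1.41 CPM in scramble (mean ± SD, n = 3 each), a log2 fold change of -1.01 ± 0.12 (SE, adjusted p = 1.08e-04), lower in 3 of 3 libraries. In the circSlc45a4 knockdown it stood at 25.1 ± 0.38 CPM, a log2 fold change of -0.39 ± 0.12 (adjusted p = 0.0245), again lower in 3 of 3 libraries. The difference between the knockdowns was 0.62 ± 0.12 (adjusted p = 0.00227). The smaller change did not pass the threshold with the Xist covariate (-0.28, adjusted p = 0.0959), against a minimum change of 1.2-fold (adjusted p = 0.206), or without scramble replicate 2 (-0.38, 0.0866) or 3 (-0.37, 0.0758) or without circSlc45a4 knockdown replicate 1 (-0.40, 0.0659), 2 (-0.40, 0.0694) or 3 (-0.38, 0.0661). Its adjusted p ranged from 0.00471 to 0.206 over all alternatives. Slc45a1 and Slc45a3, the other measured members of the family, had log2 fold changes of 0.10 and 0.01 in the circSlc45a4 knockdown and 0.06 and 0.00 in the Slc45a4 mRNA knockdown, none past the threshold.

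**Figure D1:**
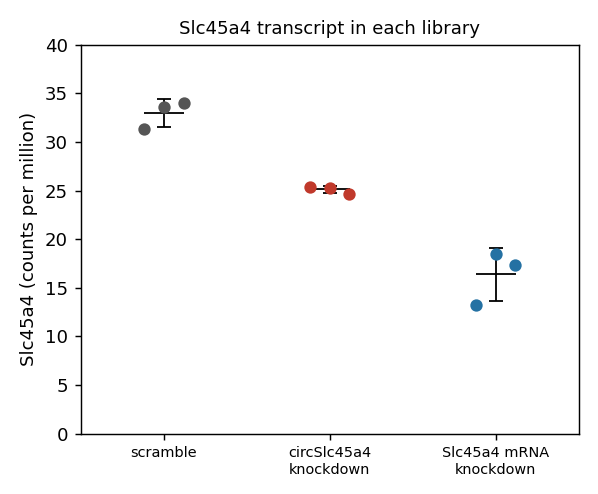
Slc45a4 transcript (CPM, axis from 0) in the 3 libraries of each group. Points are libraries, horizontal bars are means and error bars are SD. The scramble libraries lie at 31.4 to 33.96, the circSlc45a4 knockdown at 24.7 to 25.4 and the Slc45a4 mRNA knockdown at 13.3 to 18.5 CPM.

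The comparison of the circSlc45a4 knockdown with scramble asks which polyA transcripts differ when the circular RNA is targeted. Markers of apical progenitors (radial glia, the stem cells that line the ventricle) were higher, with 18 of 30 measured members higher and 1 lower (20 and 1 adjusted over the list alone). The median log2 fold change was 0.57 (adjusted p = 3.77e-08, adjusted p = 0.699 with an estimated correlation, and 1.45e-14 to 0.699 over all alternatives). Fabp7, a fatty acid binding protein of radial glia (ENSMUSG00000019874.11, chromosome 10, 57784881 to 57788450), rose from 130.1 ± 15.7 to 349 ± 37.3 CPM (log2 fold change 1.42 ± 0.11, adjusted p = 2.88e-06). Aldoc, a glycolytic enzyme enriched in radial glia and astrocytes, rose from 59.7 ± 9.62 to 164 ± 11.7 CPM, and Ttyh1 and Mt3 rose by 1.00 ± 0.11 and 1.24 ± 0.17 on the log2 scale. S phase and DNA replication genes were lower, with 19 of 36 lower and 2 higher (25 and 2 adjusted over the list alone) and a median of -0.45 (adjusted p = 2.66e-05, adjusted p = 0.967 with an estimated correlation, and 2.55e-13 to 0.967 over all alternatives). E2f1, a transcription factor of the S phase programme, fell from 54.5 ± 14.2 to 21.7 ± 1.30 CPM, and the replication genes Mcm2, Pold1 and Tyms had log2 fold changes of -0.65, -0.59 and -0.65, all past the threshold. The mean level of the S phase list (log2 CPM) overlapped between the groups, at 4.88 to 5.11 in the knockdown and 5.06 to 5.62 in scramble.

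G2 and M phase genes were also called lower against scramble, with a small median. Of 34 members 3 were lower and 0 higher (1 and 0 adjusted over the list alone), at a median of -0.29 (adjusted p = 0.0416, and adjusted p = 0.967 with an estimated correlation). The 3 were Cdc25b, a phosphatase that opens mitosis (-0.87 ± 0.12), Kif11, a spindle motor (-0.55 ± 0.19), and Hjurp, a centromere chaperone (-0.25 ± 0.08). The list call rested on single libraries. The median was -0.08 (adjusted p = 0.668) without scramble replicate 3, -0.29 (0.0608) without scramble replicate 2, -0.25 (0.121) without circSlc45a4 knockdown replicate 1 and -0.26 (0.0756) without replicate 3, and -0.47 (1.42e-06) without scramble replicate 1. Upper-quartile factors (adjusted p = 0.0576), the replicate block (0.0658), the filter on 1 CPM (0.0849) and thinning (0.0560) also ended it, and the range over all alternatives was 1.42e-06 to 0.967. Kif11 lost its call without scramble replicate 2 (log2 fold change -0.59) or 3 (-0.31) or circSlc45a4 knockdown replicate 1 (-0.49) or 2 (-0.52), and Hjurp without the same libraries (-0.26, -0.19, -0.25 and -0.22). Kif11 also lost it with the replicate block (-0.54), limma-voom (-0.53) and DESeq2 (-0.55), and both genes against a minimum change of 1.2-fold.

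Of 16 deep-layer projection neuron genes 7 were higher and 3 lower (9 and 3 adjusted over the list alone), at a median of 0.42 (adjusted p = 0.0187, and adjusted p = 0.967 with an estimated correlation). Foxp2, a transcription factor of deep cortical layers (ENSMUSG00000029563.16, chromosome 6, 14901349 to 15441977), rose from 20.6 ± 3.39 to 129 ± 26.7 CPM, and Crym, Tle4 and Fezf2 rose by 2.71 ± 0.32, 0.79 ± 0.12 and 0.65 ± 0.09 on the log2 scale. Without scramble replicate 1 the deep-layer median was 0.30 (adjusted p = 0.0746, and 3.01e-04 to 0.967 over all alternatives). Of 8 subplate genes 3 were higher and 0 lower (3 and 0 adjusted over the list alone), at a median of 0.39 (adjusted p = 0.0284, and adjusted p = 0.535 with an estimated correlation). They were Nxph4 (1.31 ± 0.20), Ccn2 (1.94 ± 0.30) and Moxd1, which stood at 0.401 CPM against 0 counts in every scramble library, and the median of 0.39 held with Moxd1 set to its floor of 3 counts per library. This list lost its call without scramble replicate 1 (0.21, adjusted p = 0.104), circSlc45a4 knockdown replicate 1 (0.22, 0.0722) or replicate 2 (0.35, 0.0606), with 0.00928 to 0.535 over all alternatives. Upper-layer genes had 3 members higher and 4 lower of 14, without a call for the list (adjusted p = 0.607). Cux2 and Pou3f3, transcription factors of upper-layer neurons, fell by 1.75 and 1.12 on the log2 scale, while Limch1 and Epha3 rose by 1.11 and 0.96.

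Genes of neurogenic commitment went both ways. Of 23 basal progenitor genes 5 were higher and 8 lower (adjusted p = 0.638 for the list), and of 23 neurogenic transcription factors 2 were higher and 5 lower (adjusted p = 0.104). Neurog1, a proneural factor (ENSMUSG00000048904.5, chromosome 13, 56250478 to 56252163), fell from 12.2 ± 3.15 to 3.95 ± 1.11 CPM, and Dll3, a Notch ligand, fell from 19.4 ± 4.84 to 8.21 ± 0.908 CPM. Scrt1, a transcriptional repressor of newborn neurons, fell from 86.9 ± 6.24 to 28.4 ± 1.68 CPM, and Tac2, a neurokinin precursor, rose by 4.24 ± 0.30 on the log2 scale. In the Notch pathway 8 of 32 members were higher and 6 lower (adjusted p = 0.326). The receptor Notch2 rose from 36.1 ± 4.61 to 147 ± 3.04 CPM and its nuclear partner Rbpj rose by 1.03 ± 0.08, while the glycosyltransferase Mfng fell by 0.89 on the log2 scale.

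Among the 12 largest rises were Parm1 (log2 fold change 4.54 ± 0.20), Unc5b, a netrin receptor (4.13 ± 0.22, from 5.67 ± 0.844 to 98.95 ± 25.3 CPM), Cybrd1, an iron reductase (3.93 ± 0.28), and Itga9, an integrin (4.12 ± 0.30). Cav1, the core protein of caveolae, Cemip, a hyaluronan binding protein, Slc26a7, Tmem117, Ltbp2, Eppk1 and Xist were also among them, at 3.78 to 11.96. Ltbp2, Eppk1 and Xist averaged 0.152, 0.0618 and 0.122 CPM in scramble, Eppk1 stood at 10.97 without scramble replicate 3, and Xist lost its call with limma-voom. The largest falls were Nptx2, a neuronal pentraxin (-4.01 ± 0.36), Nr0b1 (-3.09 ± 0.31), Gcg (-2.998 ± 0.28) and Trank1 (-2.77 ± 0.35), followed by Fibcd1, Glyctk, Mak, Angpt1, Nefl, a neurofilament subunit, Ebf3, Nr2f2 and Slc35f2, between -2.34 and -1.92. All of these had groups that did not overlap, as the rule requires.

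Markers of other cells moved at low levels. Of 14 microglia and macrophage genes 4 were higher and 0 lower (4 and 0 adjusted over the list alone), at a median of 1.26 (adjusted p = 0.0333, and adjusted p = 0.869 with an estimated correlation). The complement gene C1qa rose from 0.293 ± 0.142 to 1.02 ± 0.255 CPM, and lost its call without scramble replicate 3 (1.504) or circSlc45a4 knockdown replicate 2 (1.55). Without that knockdown replicate the list gave 1.01 (adjusted p = 0.0606). Of 9 endothelial genes 0 were higher and 2 lower (0 and 3 adjusted over the list alone), at a median of -0.60 (adjusted p = 0.0284, and adjusted p = 0.535 with an estimated correlation), or -1.43 without scramble replicate 2 and -1.29, -1.41 and -1.39 without circSlc45a4 knockdown replicate 1, 2 or 3. The filter on low counts was applied anew in these fits and kept more genes, so the measured members can differ. Without a filter and with all libraries the endothelial median was -1.46. The 2 lower genes were Slc7a5, an amino acid transporter that many cell types express (-1.42 ± 0.11), and Esam, a junction protein (-1.58 ± 0.44). Esam lost its call without scramble replicate 1 (-1.43) or 2 (-1.503) or circSlc45a4 knockdown replicate 2 (-1.49) or 3 (-1.37). The replication-dependent histones are a cell-cycle list. Of 20 such genes, whose transcripts have no polyA tail, 6 were higher and 0 lower (6 and 0 adjusted over the list alone), at a median of 1.02 (adjusted p = 0.0274, and adjusted p = 0.967 with an estimated correlation). Hist1h1c stood at 26.1 ± 14.1 against 3.96 ± 1.15 CPM. The libraries were polyA selected, so these reads show only what the selection let through and do not give the histone level. Their rise ran opposite to the S phase list (median -0.45), and the reason was not tested. The microglia, histone, subplate and endothelial calls ended when only genes at 1 CPM in 3 libraries were kept (adjusted p = 0.241, 0.0890, 0.112 and 0.0988) and after thinning to the smallest library (0.109, 0.0560, 0.0626 and 0.0560). Over all alternatives the adjusted p of the microglia, histone and endothelial lists ranged from 0.00322 to 0.869, 5.24e-04 to 0.967 and 2.06e-04 to 0.535. In the direct comparison of the knockdowns, camera in the main setting called none of the microglia, histone, subplate and endothelial lists (adjusted p = 0.341, 0.0995, 0.1855 and 0.259). Their medians in the Slc45a4 mRNA knockdown against scramble had the same signs (0.81, 0.67, 0.20 and -0.50), without a call. These changes were thus not shown to be particular to the circSlc45a4 knockdown.

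Over all genes, 2509 were higher and 2305 lower in the circSlc45a4 knockdown than in scramble, of 17760 tested, with 629 and 540 of them changed by more than 2-fold. At an unadjusted p under 0.05 there were 6837. The groups did not overlap in 43.9% of genes, where chance gives 10%. Against a minimum change of 1.2-fold 2430 genes were called. Of the calls 52.1% were higher, and 42.3% with upper-quartile factors, which moved the median of all genes to -0.06.

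**Figure D2:**
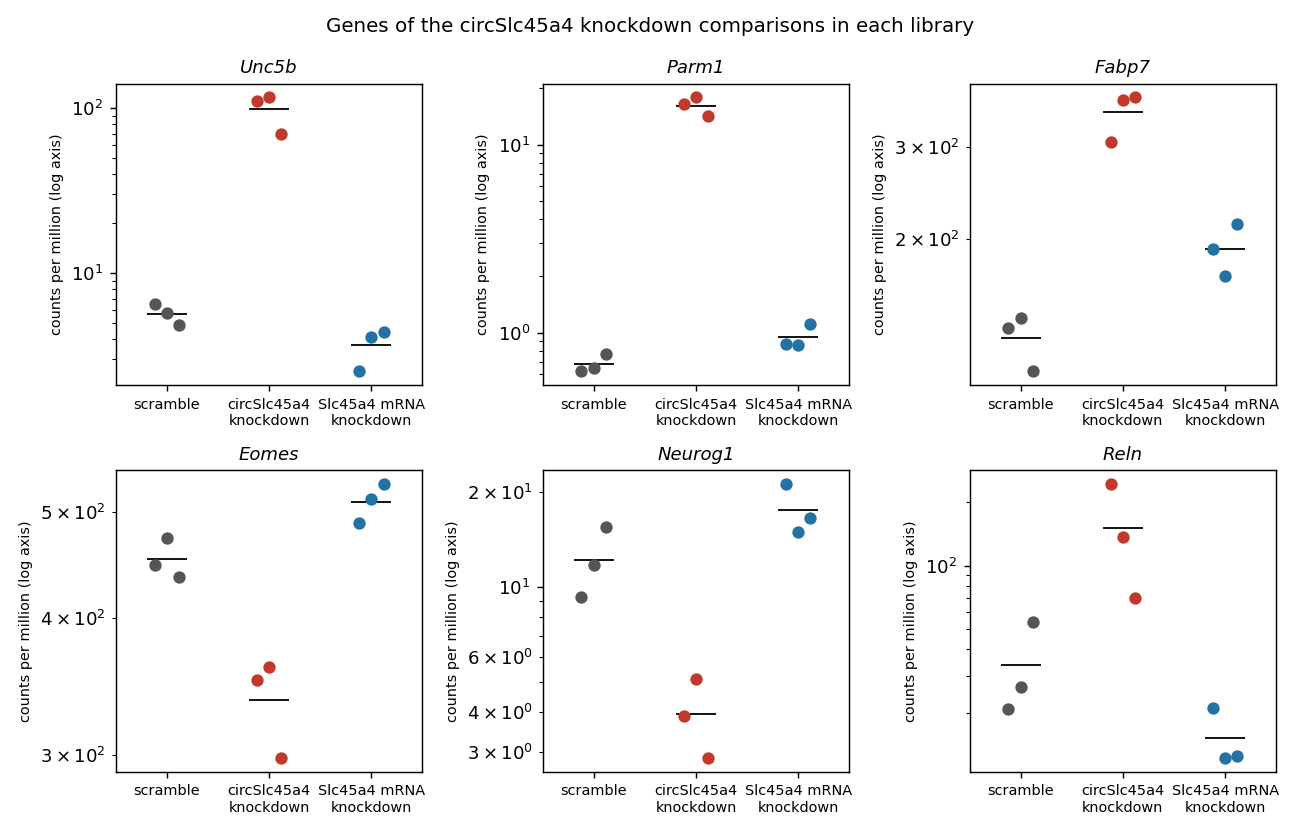
CPM (log axis) of 6 named genes in the 3 libraries of each group. Points are libraries and bars are means. Unc5b averages 98.95 in the circSlc45a4 knockdown against 5.67 in scramble and 3.68 in the Slc45a4 mRNA knockdown, and Neurog1 averages 3.95 against 12.2 and 17.6.

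The comparison of the Slc45a4 mRNA knockdown with scramble asks the same of the linear transcript. Cell-cycle genes were higher. Of 34 G2 and M phase genes 10 were higher and 0 lower (20 and 0 adjusted over the list alone), at a median of 0.45 (adjusted p = 3.01e-06, and adjusted p = 0.873 with an estimated correlation). Of 36 S phase genes 11 were higher and 1 lower (13 and 1 adjusted over the list alone), at a median of 0.31 (adjusted p = 4.95e-05, and adjusted p = 0.873 with an estimated correlation). Ect2, a regulator of cell division, rose by 1.05 ± 0.18 on the log2 scale, Cenpf, a kinetochore protein, by 0.90 ± 0.17, the clamp loader Rfc4 by 1.41 ± 0.16 (from 16.1 ± 1.42 to 42.8 ± 10.6 CPM) and the ligase Lig1 by 0.60 ± 0.12. The S phase gene that was lower was Ccne1, cyclin E (-1.18 ± 0.23, not past the threshold with the Xist covariate at -0.92). The mean levels of both lists (log2 CPM) overlapped between the groups, with G2 and M phase at 5.70 to 6.25 against 4.95 to 5.78 in scramble and S phase at 5.60 to 5.89 against 5.06 to 5.62. The size of both medians rested in part on single libraries and on Xist. The G2 and M phase median was 0.29 without Slc45a4 mRNA knockdown replicate 1, 0.30 without scramble replicate 1, 0.70 without scramble replicate 3 and 0.24 with the Xist covariate, and the S phase median was 0.20 without scramble replicate 1 (adjusted p = 0.0397) and 0.20 with the covariate (adjusted p = 0.0194). Over all alternatives the adjusted p ranged from 8.22e-16 to 0.873 for G2 and M phase and from 6.99e-10 to 0.873 for S phase.

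Genes of newborn and migrating projection neurons were lower, with 8 of 28 lower and 3 higher (15 and 3 adjusted over the list alone). The median was -0.25 (adjusted p = 0.00135, and adjusted p = 0.873 with an estimated correlation), and -0.16 without Slc45a4 mRNA knockdown replicate 1 or with the Xist covariate, both still called (adjusted p from 6.22e-06 to 0.873 over all alternatives). Stmn2, a microtubule regulator of growing neurites (ENSMUSG00000027500.10, chromosome 3, 8509360 to 8561606), fell from 440.2 ± 71.1 to 222 ± 50.6 CPM. Dcx, a microtubule protein of migrating neurons, had a log2 fold change of -0.58 ± 0.10 and Sema3c, a guidance ligand, -1.04 ± 0.17. Apical progenitor markers had 9 of 30 members higher and 3 lower in this comparison, at a median of 0.20. Their list was not called by camera (adjusted p = 0.194).

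Interferon response genes were higher, with 7 of 26 higher and 0 lower (14 and 0 adjusted over the list alone). The median was 1.69 (adjusted p = 7.26e-04, and adjusted p = 0.873 with an estimated correlation). The mean level of the list (log2 CPM) was 2.29, 0.88 and 0.53 in the Slc45a4 mRNA knockdown, -0.49, -0.06 and -0.46 in scramble, and 1.51, -0.92 and -0.83 in the circSlc45a4 knockdown. Oasl2, Ifitm3 and Usp18, which interferon induces, had log2 fold changes of 3.56 ± 1.15, 3.23 ± 0.85 and 2.71 ± 0.84 against scramble, and Eif2ak2, a sensor of double-stranded RNA, 1.13 ± 0.32. All 4 lost their calls without Slc45a4 mRNA knockdown replicate 1 (2.28, 1.93, 2.13 and 0.68), without scramble replicate 1 (3.37, 3.16, 2.55 and 0.90) or 3 (3.48, 2.92, 2.29 and 1.19) and with the Xist covariate (1.31, 1.30, 1.17 and 0.57). Oasl2 and Ifitm3 also lost theirs without scramble replicate 2 (3.89 and 3.73), as Oasl2 and Usp18 did without Slc45a4 mRNA knockdown replicate 2 (3.87 and 2.73). With limma-voom all 4 lost their calls (3.055, 2.79, 2.77 and 1.03), as Oasl2, Usp18 and Eif2ak2 did against a minimum change of 1.2-fold and Eif2ak2 with the replicate block (1.02). The list median was 1.00 without replicate 1 of that knockdown (adjusted p = 0.0431) and 0.45 with the Xist covariate (adjusted p = 0.306), within 5.07e-06 to 0.873 over all alternatives.

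The largest changes in named genes included rises of Igsf11, an adhesion protein (2.56 ± 0.21), Rpa2, a subunit of the single-strand DNA binding complex (2.07 ± 0.14, from 8.85 ± 1.94 to 37.3 ± 3.44 CPM), Ldha, lactate dehydrogenase (2.27 ± 0.17), Derl3 (2.53 ± 0.45), Mbp, a myelin protein (1.83 ± 0.22), and Minar2 (1.81 ± 0.13). Tmem117, Eda2r, Irgm1 and B2m, at 1.85 to 2.22, lost their calls with the Xist covariate (1.60, 0.95, 0.78 and 1.21). B2m also lost its call without any single scramble library (2.15, 2.38 and 2.01) without Slc45a4 mRNA knockdown replicate 1 (2.18) or 2 (1.65), with GC and length trends removed (2.02), with limma-voom (1.98) and DESeq2 (2.16), and against a minimum change of 1.2-fold. Irgm1 lost it without scramble replicate 1 (2.13) or 3 (1.98) or Slc45a4 mRNA knockdown replicate 1 (1.40) or with limma-voom (2.02), and Eda2r without scramble replicate 2 (1.68), with 1.17 without Slc45a4 mRNA knockdown replicate 1. The falls included Ccnd3, cyclin D3 (-1.73 ± 0.12, from 25.1 ± 1.76 to 7.58 ± 0.871 CPM), Stac2 (-2.42 ± 0.20), Zfp580 (-1.81 ± 0.18), Anxa5 (-1.90 ± 0.21) and Nr0b1 (-2.78 ± 0.30). Prokr2, Fam217b, Ppp1r3d, Tmem200a, Thsd7a, Trank1 and Rasa4 had log2 fold changes between -2.28 and -1.65, and Rasa4 lost its call with the Xist covariate (-1.84). Over all genes 1585 were higher and 1615 lower, with 258 and 205 of them changed by more than 2-fold, and 5702 stood under an unadjusted p of 0.05. The groups did not overlap in 36.1% of genes, against 10% by chance. The count was 1553 with the Xist covariate (850 higher and 703 lower, so that the balance turned), 1760 without scramble replicate 2 and 1197 against a minimum change of 1.2-fold.

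The direct comparison of the knockdowns tests whether their effects differ, and the scramble libraries do not enter its contrast. Cell-cycle genes were lower in the circSlc45a4 knockdown than in the Slc45a4 mRNA knockdown. Of 36 S phase genes 33 were lower and 1 higher (33 and 1 adjusted over the list alone), at a median of -0.81 (adjusted p = 1.20e-18, and adjusted p = 0.883 with an estimated correlation). Of 34 G2 and M phase genes 28 were lower and 0 higher (32 and 0 adjusted over the list alone), at a median of -0.79 (adjusted p = 1.64e-12, and adjusted p = 0.883 with an estimated correlation). Over all alternatives the adjusted p ranged from 1.17e-30 to 0.883 for S phase and from 4.54e-22 to 0.883 for G2 and M phase. Lig1, E2f1, the cyclin Ccne2 and the replication licensing factor Cdc6 had log2 fold changes of -1.09 ± 0.12, -1.17 ± 0.15, -1.34 ± 0.18 and -1.33 ± 0.19, and Cdc25b, Cenpf and Kif11 had -1.32 ± 0.12, -1.11 ± 0.17 and -1.05 ± 0.19. The mean levels of both lists did not overlap between the knockdowns, with S phase at 4.88 to 5.11 against 5.60 to 5.89 and G2 and M phase at 5.06 to 5.26 against 5.70 to 6.25 (log2 CPM). Xist was high in every circSlc45a4 knockdown library and in 2 of the 3 Slc45a4 mRNA knockdown libraries.

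**Figure D3:**
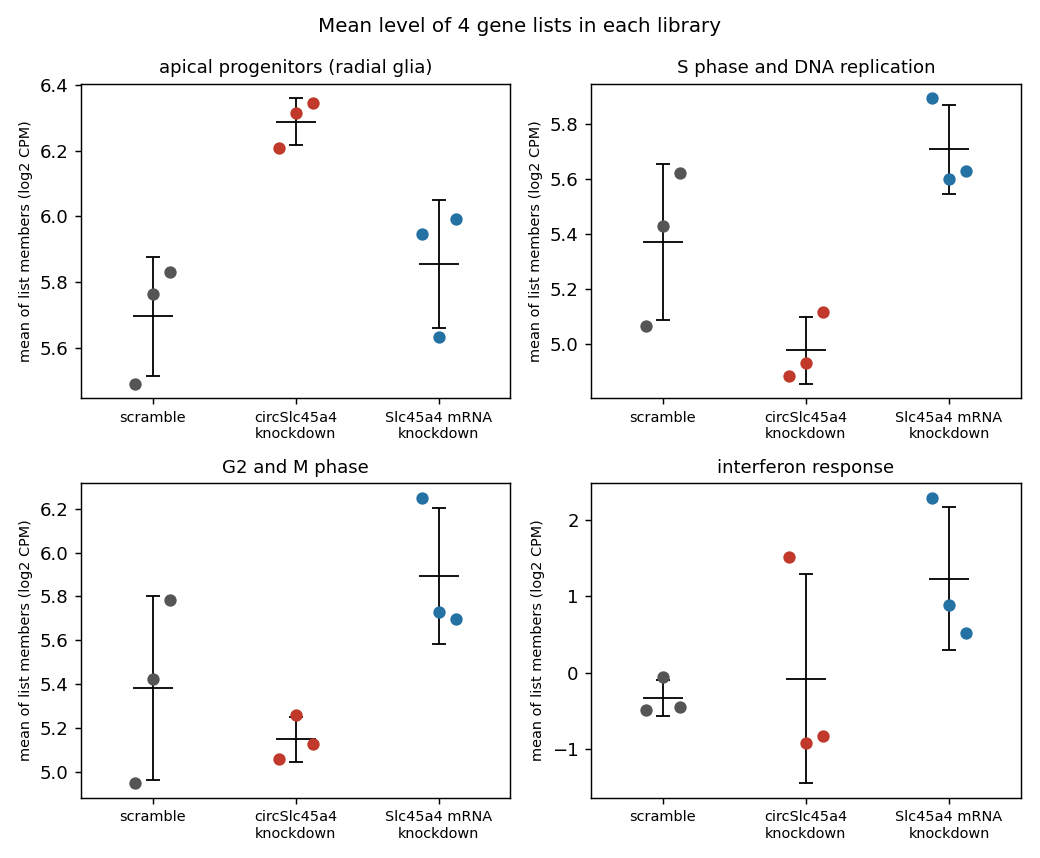
Mean of the members of 4 gene lists (log2 CPM) in the 3 libraries of each group. Points are libraries, horizontal bars are means and error bars are SD. The apical progenitor mean is 6.29 in the circSlc45a4 knockdown against 5.70 in scramble, and the interferon mean varies within both knockdowns.

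Apical progenitor markers were higher in the circSlc45a4 knockdown in this comparison too, with 13 of 30 higher and 3 lower (15 and 3 adjusted over the list alone). The median was 0.37 (adjusted p = 2.15e-05, and adjusted p = 0.883 with an estimated correlation), and 0.25 without Slc45a4 mRNA knockdown replicate 2, with an adjusted p from 1.89e-09 to 0.883 over all alternatives. Mfge8, Ttyh1, Aldoc and Fabp7 were higher by 1.39 ± 0.17, 0.99 ± 0.11, 0.95 ± 0.12 and 0.86 ± 0.11 on the log2 scale. Basal progenitor genes had 6 members higher and 6 lower of 23 (adjusted p = 0.607). Eomes, the transcription factor that marks basal progenitors (ENSMUSG00000032446.14, chromosome 9, 118478212 to 118486132), stood at 336 ± 33.7 against 510.5 ± 21.1 CPM (log2 fold change -0.60 ± 0.08). Neurog1 stood at 3.95 ± 1.11 against 17.6 ± 3.27 CPM and Dll3 at 8.21 ± 0.908 against 23.5 ± 2.71 CPM. Deep-layer genes were higher, 5 of 16 with 2 lower (7 and 4 adjusted over the list alone), at a median of 0.28 (adjusted p = 0.0406, and adjusted p = 0.883 with an estimated correlation). That call was lost without circSlc45a4 knockdown replicate 2 (0.32, adjusted p = 0.0893) or Slc45a4 mRNA knockdown replicate 2 (0.27, 0.0670) or 3 (0.23, 0.183), and the median was 0.17 without circSlc45a4 knockdown replicate 1. The filter on 1 CPM (0.0810), the replicate block (0.0573) and removal of GC and length trends (0.0914) ended it too, with 0.00181 to 0.883 over all alternatives. Foxp2 was higher by 2.56 ± 0.16 and Ldb2, a cofactor of LIM factors, was lower at -1.13 ± 0.13.

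Cytosolic ribosomal protein genes were slightly lower, with 7 of 39 lower and 0 higher (6 and 0 adjusted over the list alone), at a median of -0.17 (adjusted p = 9.34e-04, adjusted p = 0.883 with an estimated correlation, and 2.77e-08 to 0.883 over all alternatives). Interferon genes were lower, 2 of 26 with 0 higher (1 and 0 adjusted over the list alone), at a median of -0.88 (adjusted p = 0.0363, and adjusted p = 0.883 with an estimated correlation). That call was lost without circSlc45a4 knockdown replicate 2 (-0.43, adjusted p = 0.156) or 3 (-0.58, 0.150), without Slc45a4 mRNA knockdown replicate 1 (-0.14, 0.304) and with the Xist covariate (-0.42, 0.0964), and the median was -2.66 without circSlc45a4 knockdown replicate 1. Upper-quartile factors (0.0704), the filter on 1 CPM (0.0946) and removal of GC and length trends (0.0532) ended it too, with 7.22e-08 to 0.883 over all alternatives. The 2 genes were Ifit2 (-0.89 ± 0.17) and Ifi27 (-2.87 ± 0.93), and Ifi27 lost its call without circSlc45a4 knockdown replicate 2 (-2.35) or 3 (-2.34) or Slc45a4 mRNA knockdown replicate 1 (-1.93) or 2 (-3.07), with DESeq2 (-2.89) and against a minimum change of 1.2-fold, and stood at -6.03 without circSlc45a4 knockdown replicate 1. Of 12 Cajal-Retzius genes 3 were higher and 1 lower (adjusted p = 0.401). Reln, the secreted protein of these cells, stood at 150.3 ± 87.8 against 15.2 ± 5.10 CPM (3.30 ± 0.43), Nhlh2 and Ndnf were higher by 2.47 ± 0.42 and 1.55 ± 0.35, and Ebf3 was lower at -1.43 ± 0.27.

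Among single genes, Unc5b (4.75 ± 0.23), Parm1 (4.08 ± 0.19), Bves (4.34 ± 0.32), Tac2 (4.05 ± 0.29) and Stac2 (3.44 ± 0.20) were far higher in the circSlc45a4 knockdown than in the Slc45a4 mRNA knockdown, with Cav1, Ltbp2, Hmcn1, Trim47, Eppk1 and Ebf1 at 3.46 to 6.33 (10.95 for Eppk1 without Slc45a4 mRNA knockdown replicate 3). Derl3 (-3.76 ± 0.48), Nptx2 (-3.57 ± 0.36), Gprin3 (-2.52 ± 0.27), Scrt1 (-1.80 ± 0.14) and Ung, uracil DNA glycosylase (-1.92 ± 0.20), were lower. So were Trim66, Slco1c1, Gcg, Cacng5, Slc7a14 and Slc2a4, at -2.35 to -1.81, and Slco1c1 lost its call without circSlc45a4 knockdown replicate 1 (-1.89) or 2 (-1.74) or Slc45a4 mRNA knockdown replicate 3 (-1.65), and stood at -3.44 without circSlc45a4 knockdown replicate 3. Over all genes 2445 were higher and 2187 lower, with 455 and 431 of them changed by more than 2-fold, and 6722 stood under an unadjusted p of 0.05. The groups did not overlap in 40.1% of genes, against 10% by chance. The count was 3059 without circSlc45a4 knockdown replicate 1 and 2073 against a minimum change of 1.2-fold. Of the calls 52.8% were higher, and 42.1% with upper-quartile factors, which moved the median of all genes to -0.07.

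Against scramble, 879 genes were called higher in both knockdowns, 612 lower in both and 125 in opposite directions. The overlap that the shared scramble libraries alone would give was not simulated. Thap12, Slc39a9, Ldha, Minar2, Ptges3, a cochaperone of Hsp90, and Rbpj had the smallest p in both, all higher. Ldha rose from 43.8 ± 9.85 CPM in scramble to 256 ± 30.0 and 212 ± 38.0 CPM, and the other 5 rose by 1.03 to 1.92 on the log2 scale in the circSlc45a4 knockdown and by 1.07 to 1.81 in the Slc45a4 mRNA knockdown. Nr0b1 and Trank1 were among the largest falls in both. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.516 and Spearman's rho 0.455. Both comparisons use the same 3 scramble libraries, and simulated unchanged groups gave a mean r of 0.524 (0.5002 to 0.539), so the measured r lay within the range that the shared control alone gave. The fold changes had the same sign in 65.9% of genes, against 67.1% in the simulations. The covariance was 0.194, against 0.0543 in the simulations (0.0495 to 0.0577), above the highest simulated value. The 3 control libraries cannot be divided into independent sets of 2.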

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

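The tests for sex, depth, single libraries and sequence matches of the cell-cycle pattern were written before their results were seen, the settings for sex and depth were added after the data were seen, and the sequence words were extended from 1 to 3 per group, and to coding sequences, after a first result was seen. Groups of 3 libraries were not searched for outlying samples. The results here stand out because the knockdowns moved them in opposite directions against scramble, with the difference itself tested (circSlc45a4 knockdown minus Slc45a4 mRNA knockdown, edgeR, log2). S phase genes differed by a median of -0.81 and G2 and M phase genes by -0.79. Lower in the circSlc45a4 knockdown were Cdc25b (-1.32), Hjurp (-0.51), Lig1 (-1.09), Cacng5 (-1.95), Gprin3 (-2.52), Ndrg1 (-1.50) and Plk2 (-1.09). Higher were Apcdd1 (2.18), Bves (4.34), Ccnd3 (2.41), Nrp2 (1.27) and Stac2 (3.44). The circSlc45a4 side against scramble was weak for some of these. For G2 and M phase 3 of 34 genes were lower (1 adjusted over the list alone) at a median of -0.29 (adjusted p = 0.0416), and the call was lost without scramble replicate 3 (-0.08, adjusted p = 0.668) or 2 (0.0608) or circSlc45a4 knockdown replicate 1 (0.121) or 3 (0.0756), with 1.42e-06 to 0.967 over all alternatives. Scramble replicate 1, at a mean of 4.95 log2 CPM, lay below the circSlc45a4 knockdown libraries (5.06 to 5.26). Hjurp lost its call there without scramble replicate 2 (-0.26) or 3 (-0.19) or circSlc45a4 knockdown replicate 1 (-0.25) or 2 (-0.22), and Plk2 without scramble replicate 2 (-0.35) or against a minimum change of 1.2-fold, as Hjurp did. The alternatives were not run against scramble for Bves, Cacng5, Gprin3 and Nrp2. The 2 S phase calls against scramble, and those for G2 and M phase, are lost with an estimated correlation, as is the direct call (adjusted p = 0.883). All of them are lost with fry too. Its adjusted p for S phase was 0.169, 0.213 and 0.0580 in the circSlc45a4, Slc45a4 mRNA and direct comparisons. For G2 and M phase it was 0.522, 0.222 and 0.108.

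The cell-cycle genes lower in the circSlc45a4 than in the Slc45a4 mRNA knockdown were weighed against 4 technical explanations. All values here are from that direct comparison. It holds both a fall of the first knockdown and a rise of the second against scramble. Those medians were -0.45 and 0.31 for S phase and -0.29 and 0.45 for G2 and M phase. The values below therefore do not test the fall against scramble by itself. With the Xist level as a covariate the S phase median was -0.73, after thinning to the smallest library it was -0.80, and the value nearest to 0 with 1 library left out was -0.66, without Slc45a4 mRNA knockdown replicate 1. The 15 S phase genes without any of the 3 sequence words of each group had a median of -0.85, and 14 of them were lower (23 genes, -0.83 and 21 with the first word of each group alone), and the 12 without any circSlc45a4 knockdown word in the 3' UTR or coding sequence had a median of -0.77, with 10 lower. For G2 and M phase the median was -0.66 with the Xist covariate and -0.76 after thinning. The 20 genes without the words of each group in the 3' UTR had -0.86. The 12 without a circSlc45a4 knockdown word in either sequence had -0.79, with 9 lower. With the words of every group in either sequence, 0 G2 and M phase and 3 S phase genes were left, too few to decide. Thinning keeps the expected fold change of well-read genes, so the values after thinning cannot decide on depth. The other values argue against sex, these words in 3' UTRs, or the circSlc45a4 knockdown words in either sequence as the whole cause of the direct difference. For S phase they also argue against 1 library. A difference in the share of cycling cells between the knockdowns may underlie the pattern as a hypothesis found on these data, and neither that share nor indirect effects of the shRNAs were tested.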

How the results depend on the processing

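Thinning, the Xist covariate and removal of GC and length trends were chosen after seeing the data, and no named gene or list past its threshold turned its direction under any alternative run, while some without a call did. The balance of the genes called did turn. With upper-quartile factors 2094 were higher and 2854 lower in the circSlc45a4 and 2022 and 2785 in the direct comparison (2509 and 2305, 2445 and 2187 as reported), and in the Slc45a4 mRNA comparison the share higher (49.5%) ranged from 45.6% to 54.7%. Among named genes, leaving 1 library out in turn kept the side of the threshold in 2616 cases, lost it in 284 and gained it in 28. Against a minimum change of 1.2-fold the genes called were 2430, 1197 and 2073 in the circSlc45a4, Slc45a4 mRNA and direct comparisons, fewer by construction, and Slc45a4 in the circSlc45a4 knockdown (-0.39) was not called. With the Xist covariate that value was -0.28 and 1553 genes were called in the Slc45a4 mRNA knockdown. With 1 library left out the genes called ranged from 3386 to 4248, from 1760 (without scramble replicate 2) to 2764, and from 3059 (without circSlc45a4 knockdown replicate 1) to 4101. Slc45a4 ranged from -0.43 to -0.37 and from -1.11 to -0.87. Of the lists, 8, 4 and 6 were called. With an estimated correlation camera called 0, 0 and 0 (2, 1 and 0 at an unadjusted p under 0.05), and fry called 7, 2 and 0. These were in part other lists. In the circSlc45a4 comparison fry added neurogenic transcription factors, oligodendrocyte precursors and Wnt genes. In the Slc45a4 mRNA comparison it called only oligodendrocyte precursors and endothelial genes, which camera had not called. Fry called no S phase or G2 and M phase list in any comparison. Without a filter 10 lists were called in the Slc45a4 mRNA and 10 in the direct comparison. With 1 CPM in 3 libraries 3 were called in the circSlc45a4 knockdown, and 3 after thinning. With 1 library left out the lists called ranged from 7 to 8, from 5 to 8 (8 without Slc45a4 mRNA knockdown replicate 3, 7 without replicate 2) and from 4 (without circSlc45a4 knockdown replicate 2) to 8. The agreement of the knockdowns was 0.455 by ranks, 65.9% by sign (67.1% in simulated unchanged groups), 0.575 over genes called in either comparison (simulated 0.516, 0.484 to 0.554), and 0.581 to 0.622 without 1 scramble library, for which no simulation was run. The simulation over called genes used the genes called in the measured data, not genes called in the simulated counts. Choosing genes by their measured change can raise r, so a value of 0.575 above that range decides nothing. Except where fewer genes or libraries entered, the cause was not tested. Depth limits genes near the floor of 3 counts per library.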

Other observations

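Several other groups were measured without a call for the list, by edgeR and camera. In the circSlc45a4 knockdown against scramble, 3 of 4 oligodendrocyte precursor genes were higher (adjusted p = 0.103), among them Olig2 (log2 fold change 2.64) and Tnr (1.04). The Slc45a4 mRNA knockdown against scramble also had 2 of 4 higher (0.0761), and the direct comparison gave no call (median 0.11, 0.949). In the circSlc45a4 knockdown against scramble, 7 of 19 Wnt genes were higher and 3 lower (0.180), with Tcf7l2 at 1.70 and Nkd1 at -1.06. Of 11 Hedgehog genes 3 were higher (0.326), with Gli3 at 0.74. Among 30 axon guidance genes 7 were higher and 9 lower (0.722), with the ligand Slit1 at -1.74, and among 28 synapse genes 6 and 7 (0.843), with Syt1 at -1.25. Of 28 newborn neuron genes 5 were higher and 8 lower (0.476), of 13 ventral inhibitory neuron genes 1 and 3 (0.650), and of 12 Cajal-Retzius genes 3 and 1 (0.740). Of 14 small RNA genes 2 were higher and 5 lower (0.722), with Ago2, the slicing Argonaute, at 1.43 and Drosha at -0.44. Of 18 glycolysis genes 4 were higher and 6 lower (0.495), with Ldha at 2.54 and Eno1 at -1.42.

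For the rest of the lists in that comparison, the higher and lower counts were 5 and 1 of 17 for hypoxia (adjusted p = 0.180), 6 and 2 of 26 for immediate early genes (0.445) and 7 and 3 of 24 for the unfolded protein response (0.775). They were 7 and 1 of 36 for the respiratory chain (0.476), 2 and 0 of 15 for mitochondrially encoded genes (0.403), 2 and 4 of 39 for ribosomal proteins (0.326), 1 and 3 of 20 for cholesterol synthesis (0.868), 2 and 3 of 24 for p53 targets (0.962) and 2 and 2 of 13 for exit inhibitors (0.754). They were 2 and 1 of 7 for pericytes (0.775), 0 and 1 of 4 for meningeal fibroblasts (0.920), 1 and 0 of 3 for choroid plexus with cortical hem (0.962) and 0 and 1 of 3 for the SLC45 family (0.775). Interferon genes (0 of 26, adjusted p = 0.714) and erythroid genes (0 of 5, 0.868) had no member past the threshold. The median and mean differed in sign for basal progenitors (-0.05 and 0.06), p53 targets (-0.12 and 0.00), the unfolded protein response (0.09 and -0.03), the SLC45 family (0.01 and -0.09), glycolysis (0.01 and -0.04), cholesterol synthesis (-0.08 and 0.01) and the choroid plexus list (0.14 and -0.52).

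The tests on sequence words, the covariance test of the shared scramble libraries, the test of the words as the whole cause and the test of a state of single libraries were chosen only after the results were seen. The covariance replaced the correlation after r was found inside the simulated range.

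The 879 genes higher in both knockdowns than in scramble were weighed first. The covariance of the fold changes over all genes exceeded the simulated mean by 0.140, which argues against chance noise in the shared scramble libraries as its whole cause. Scramble libraries that truly differ would also raise it, and the overlap of 879 genes was not simulated. After thinning 89.2% of the genes (784) stayed higher in both, and 96.6% (849) with GC and length trends removed. The second share argues against GC content and gene length as the whole cause. Thinning keeps the expected fold change of well-read genes, so the first share does not decide on depth. With the Xist covariate 62.8% (552) stayed so, and sex stays open for these genes, since every scramble library lacks Xist. A candidate explanation is that the scrambled shRNA lowered transcripts through short matches in their 3' UTRs: in a random part of the genes AGTCGAT was tied to low expression in scramble (t = -9.71, highest of 100 permutations 5.40) and in the held-out part t was -9.25, with a median difference of -0.32 over 81 genes. That word was reached only after a first search, limited to words in at least 225 genes, gave none beyond the permutations (t = -4.46 against 4.94), and after an enrichment over all genes had shown GTCGAT, so the held-out part is not independent of the choice. At least 1 of 3 such 6-base words, chosen over the same genes, stood in the 3' UTR of 28.0% of the 768 searched genes (9.29% of others) and in the 3' UTR or coding sequence of 52.9% (26.0% of others), and direct matches as the whole cause cannot be told apart from indirect changes, because other words were not searched in the rest and the shRNA sequences are not available here.

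The same search gave AAGCCGC for low expression in the circSlc45a4 knockdown (held-out t = -4.78, median difference -0.15 over 135 genes) and CCACACA in the Slc45a4 mRNA knockdown (held-out t = -6.43, -0.04 over 990 genes). In the coding sequences of the held-out genes t was -2.25 for AAGCCGC, -5.74 for CCACACA and -4.58 for AGTCGAT. The tie of CCACACA and AGTCGAT was thus not limited to 3' UTRs, while the weaker value for AAGCCGC leaves this open for that word. Each group was set against the other 2, so a word low in 1 group appears high in another, and high words of this kind decide nothing about matches. TCCACAC, high in scramble (t = 6.77, held-out t = 4.10), was low in the Slc45a4 mRNA knockdown (t = -11.3 over all genes searched). GTCGATC, high in the circSlc45a4 knockdown (t = 5.72, held-out t = 0.412), was low in scramble (t = -8.96), and TAGCCGC, high in the Slc45a4 mRNA knockdown (t = 5.35, held-out t = 0.883), was low in the circSlc45a4 knockdown (t = -6.79). GTCTGAT, high in the Slc45a4 mRNA knockdown (t = 5.69, held-out t = 3.66, words in at least 225 genes), was not among the strongest low words of another group. Off-target matches of these shRNAs are a candidate explanation that stays open beside other properties of the genes with these words, and the effects per gene were small.

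The higher interferon genes of the Slc45a4 mRNA knockdown were weighed as the last pattern. Microglia in the GFP-sorted cells cannot be told apart from other sources, since the relation of the list means over 9 libraries is too few points to decide (Pearson's r = 0.0250, exact permutation p = 0.948, Spearman's rho -0.0333, exact p = 0.948, 1 relation computed, r = 0.197 without the 2 farthest libraries). The microglia list lay higher in that knockdown than in scramble as well, without a call (median 0.81, adjusted p = 0.194, means of -0.51, 0.09 and -0.25 against -0.73, -0.84 and -1.22 log2 CPM, C1qa at 0.512 against 0.293 CPM), and higher still in the circSlc45a4 knockdown (0.11, 0.59 and 0.01), where interferon genes had no call. The median was 0.45 with the Xist covariate. Sex is hard to tell apart from the groups, because every scramble library lacks Xist and only replicate 3 of the Slc45a4 mRNA knockdown lacks it. That library had an interferon mean of 0.53, above the scramble libraries (-0.49, -0.06 and -0.46), but 1 library cannot decide. Also, 2 of the 5 libraries with Xist lie below every library without it. A state of single libraries is a candidate explanation, since the SD within all 3 groups pooled was 0.971 against a difference of 1.57 between the group means. Also, circSlc45a4 knockdown replicate 1 lay above the lowest Slc45a4 mRNA knockdown library. The SD was 1.38 in the circSlc45a4 knockdown, 0.936 in the Slc45a4 mRNA knockdown and 0.240 in scramble, and the last 2 groups did not overlap. With the replicate block the camera call stayed (median 1.18, adjusted p = 9.33e-06). An effect of the knockdown itself stays open.

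Other splits of the libraries were counted. For each pair of groups 1 of 10 splits, the real one, gave as many genes, with 4814, 3200 and 4632 genes by edgeR against a highest other of 0 (670, 1069 and 1137 at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05. For the 3 groups together 1 of 100 splits, drawn from 280, gave as many. It was the real one, with 6860 genes against a highest other of 1902. A random division of the libraries is thus unlikely to give that count, and 1 in 100 is the smallest share these splits can reach. They cannot tell the shRNAs apart from sex, depth or anything else that follows the groups.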
